A study of Arabidopsis thaliana with 69 samples.

How the data were processed

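The data were Affymetrix ATH1 gene expression values of Arabidopsis thaliana seedlings of ecotype Col-0. Per the labels, seedlings were grown in the dark for 6 days in liquid culture and then given 10 µM dexamethasone (DEX) or its solvent DMSO. DEX moves a protein fused to the hormone-binding part of the glucocorticoid receptor (GR) into the nucleus. The line of interest carried VND7-VP16-GR, a fusion of the xylem transcription factor VND7 with the VP16 activation domain and GR. The empty-vector line carried VP16-GR without VND7. The labels name hypocotyl as the tissue. There were 69 arrays in 23 groups of 3, with 51 arrays of the VND7 line and 18 of the empty-vector line. In the VND7 line 24 arrays carried a DEX label and 27 a DMSO label, of which 3 were harvested at 0 h.

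The deposited values were log2 signals per probe set, which the submitters' processing notes attribute to GCRMA, with its version not given. The range of the values and their common floor of 2.14 went with that unit. No scaling was added for the main values. Array medians ran from 4.89 to 5.60, and 27.7% to 32.2% of the values of an array lay at the floor. Here and below, a value or group mean counts as at the floor when it is less than 0.3 above it. The files held 22810 probe sets. The 64 control probe sets were left out, and 22746 were tested. Of the probe sets, 13513 named 1 gene, 503 several genes and 8730 were used without a gene name. Of those with 1 gene, 13436 matched the reference gene names by locus and 77 did not. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it in the list tests, which gave 13356 genes. Gene symbols are those of the files and the reference table, and a locus code is printed where they give no symbol. No coordinates are given, because no genome build was used. No probe set used here names VND7, so its level is not reported here.

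The test was limma 3.58.1 in R 4.3.3. One mean per group was fitted to all 69 arrays, and moderated statistics were computed with a prior that follows the mean signal. A probe set was called when its Benjamini-Hochberg adjusted p within the comparison was under 0.05 and its change was at least 1 on the log2 scale, both directions tested. There were 25 comparisons: DEX against DMSO at each of 8 times in the VND7 line and 3 times in the empty-vector line, the difference of these effects between the lines, the lines without DEX, later DMSO arrays against 0 h, changes of the effect between times, and averages. Standard errors are those of the fit, and other errors are standard deviations of 3 arrays. The p-values and standard errors rest on 1 spread per probe set taken over all 69 arrays, not over the compared arrays alone. Arrays elsewhere in the series can therefore widen or narrow them. The number of arrays limits the precision. Comparisons that use the same arrays are not independent of each other.

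The comparisons, the thresholds, 25 gene lists of 463 loci, most of the alternatives and the rule for named genes were set before the data were examined. The rule names members of these fixed lists. At each time in the VND7 line it also names the 10 largest rises and 10 largest falls among called probe sets of 1 gene whose 3 DEX arrays all lie on one side of the 3 DMSO arrays. For each other comparison it names the 5 largest in each direction, without the one-sided condition for averages and differences of effects. VND7 was to be named first, which could not be done. Members of further lists are also named as examples, and these examples were chosen after their values were seen.

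Only 4 of the fixed lists had at least 5 measured members under their gene names, 18 had fewer and 3 had none. Therefore 17 lists were added, after the coverage of gene names and the medians, principal components and correlations of the arrays had been seen, but before the change of any gene was computed. One of these, of 24 loci, was written from memory of genes co-expressed with secondary wall genes in the xylem literature, and which of them earlier VND studies had picked was not traced. The others are families picked by symbol. The 21 lists with at least 5 members were tested with camera at its preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares a list with the other genes. It was repeated with a correlation estimated from the arrays. Fry, which tests whether the genes of a list move one way without comparing them with other genes, was run beside it. For a fixed list, calls adjusted over the list alone are given too.

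The method was tested on simulated values, with changes added to the 9 h comparison. No measured values were used directly: they were drawn at random for each probe set from its mean and residual spread. The probe sets given a change were drawn from those with a mean of at least 5, so the call rates do not cover dimmer ones. Of 50 probe sets each, limma called 76% at a size of 1.5, 78% at 2, 86% at 3 and 96% at 4 on the log2 scale, with 8 unchanged probe sets called among 22746. Camera gave p under 0.05 for 100 of 100 lists of 10 genes shifted by 1, and for 5 of 100 lists left unshifted. The simulation had no correlation between genes and no arrays out of place, so these rates need not hold for the real values.

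The alternatives were a filter on dim probe sets with all group means under 5, a prior that does not follow the signal, a robust prior, quantile normalization, median centring of each array, a fit of the compared groups only, no minimum change, adjustment pooled over comparisons of a kind, array weights, replicate number as a block, and each array left out in turn. Replicate numbers did not pair the samples: in 8 of 24 VND7-line pairs and 1 of 9 empty-vector pairs the correlation of DEX and DMSO residuals exceeded 0.1. For lists, the mean of a gene's probe sets was also tried. One alternative was added after the data had been seen: leaving out 10 arrays of the VND7 line that stood out of place. These were 9 arrays whose median correlation was higher with arrays of the other treatment label of the line, and arrays whose 2 closest arrays both carried the other label. They were picked from the same values, so this alternative favours a larger difference between DEX and DMSO. No array was moved to another group. Other splits of the compared arrays were fitted in the same way, all 10 of them for 3 arrays against 3 and 100 random draws for differences, changes and averages.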

Results

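The series followed dark-grown Arabidopsis cultures for up to 48 h after induction of VND7-VP16-GR, a DEX-activated form of VND7, the transcription factor that specifies xylem vessels. DEX was compared with DMSO in 3 arrays each at 1, 3, 6, 9, 12, 24, 30 and 48 h, with 3 more DMSO arrays at 0 h. An empty-vector line with VP16-GR alone was measured with and without DEX at 9, 12 and 24 h, to see what DEX did without VND7. Signals are log2 values per probe set. With 3 arrays in a group, their number limits the precision.

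Some arrays of the VND7 line sat with the other treatment label. The first principal component held 68.4% of the variance, and 9 arrays correlated better with arrays of the other label than with their own, 3 labelled DMSO and 6 labelled DEX. By this rule or by their closest neighbours 10 arrays were out of place: DMSO 0 h replicate 3, DMSO 1 h replicate 2, DMSO 6 h replicate 2, DMSO 24 h replicate 1, DEX 1 h replicates 2 and 3, DEX 24 h replicate 2, and all 3 DEX arrays at 48 h. The mean of 24 genes listed for xylem and secondary walls was 8.80, 8.48 and 8.54 in the arrays labelled DMSO 1 h replicate 2, 6 h replicate 2 and 24 h replicate 1. It was 7.60 at DMSO 0 h replicate 3 and 5.19 to 5.90 in the other DMSO arrays of the line. In the arrays labelled DEX 48 h it was 5.72 to 5.94, and at DEX 1 h replicate 3 it was 5.42. At DEX 1 h replicate 2 and DEX 24 h replicate 2 it was intermediate, 7.31 and 7.26, near that of DMSO 0 h replicate 3. The VND7 line counts below are therefore given with all arrays and again without these 10, a choice made after the data were seen. These arrays were picked from the same values by how they correlate with the treatment labels, so leaving them out raises the DEX counts by construction and is no independent check.

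**Figure D1:**
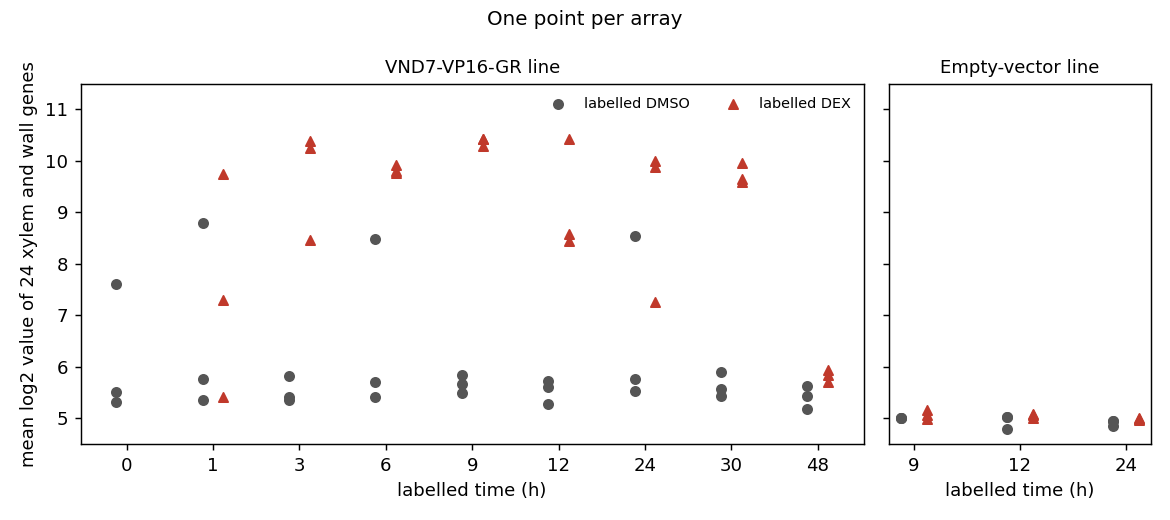
Each point is 1 array: the mean log2 value of 24 genes listed for xylem and secondary walls (vertical axis) at each labelled time in hours, with DMSO as circles and DEX as triangles. The array labelled DMSO 1 h replicate 2 sits at 8.80, while the DEX arrays at 48 h sit at 5.72 to 5.94.

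At 1 h of DEX 1 probe set rose and 2 fell. AT1G22630 rose by 1.05 ± 0.22 (SE) on the log2 scale, from 3.92 ± 0.07 to 4.97 ± 0.21 (SD, n = 3). AT3G10190 fell, with a log2 change of −1.99 ± 0.37 (SE). The xylem genes were not called: AT1G66810 read 6.92 ± 4.12 against 4.68 ± 3.69 (DEX against DMSO, SD, n = 3). At an unadjusted p under 0.05 limma gave 1765 probe sets. Leaving out DMSO replicate 1 gave 7 calls, and leaving out DEX replicate 1, 2 or 3 gave 25, 99 or 312. A fit of the compared groups only gave 0. Without the arrays out of place 6950 probe sets were called, with 1 DEX array left, which is assumed to vary like the other groups. This array, DEX replicate 1, formed a trio of mutually nearest arrays with DEX 30 h replicates 2 and 3 (lowest r = 0.977). It read 10.85 for the cell death gene ALPHA-VPE, against 10.86, 11.23 and 10.81 in the 30 h arrays and 7.71, 4.69 and 5.98 in those of 3 h. The 6950 calls therefore rest on an array with a profile like that at 30 h.

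**Figure D2:**
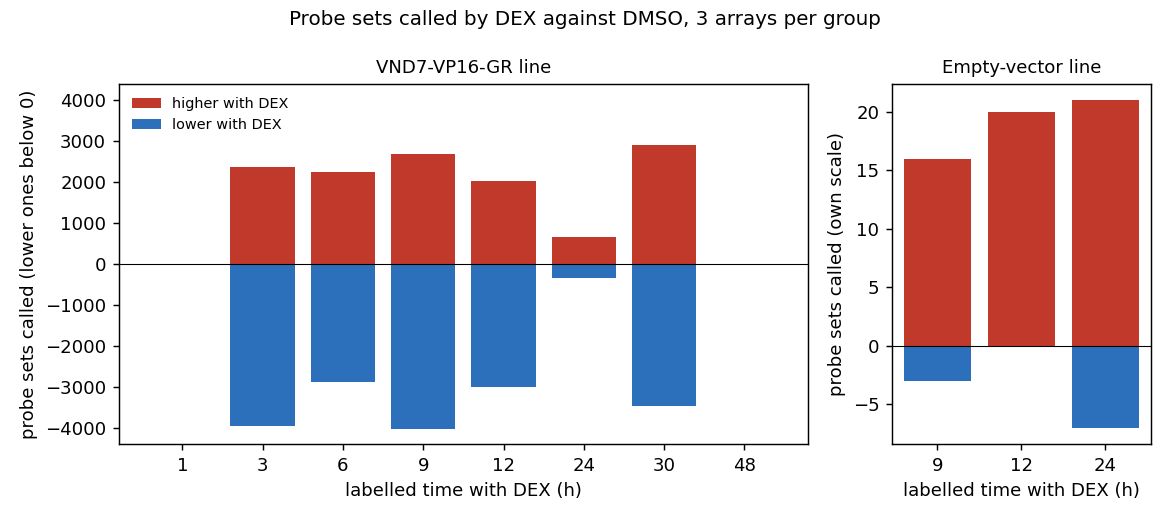
Bars give the number of probe sets called higher (above 0) and lower (below 0) with DEX than with DMSO at each labelled time in hours, 3 arrays per group, with the VND7 line on the left and the empty-vector line on the right on its own scale. The VND7 line had 2683 higher and 4019 lower at 9 h, and the empty-vector line 16 and 3.

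By 3 h 2370 probe sets had risen and 3947 had fallen. AT1G66810, a CCCH zinc finger gene of the fixed list of secondary wall regulators, rose by 9.29 ± 1.40 (SE), from 2.80 ± 0.12 to 12.08 ± 0.59 (SD, n = 3, adjusted p = 7.6e-07). Other steep rises were AT2G45040 at 9.00, AT5G49690 at 8.54, AT1G29200 at 8.42, AT5G45320 at 8.37 and AT1G75090 at 7.83. The xylan synthesis genes GUT2, IRX15 and IRX15-L rose by 5.12, 6.06 and 4.95. Among the falls were AT1G80130 at −7.27, the glutathione transferase gene GSTU20 at −6.78, AT4G25260 at −6.54, AT1G29660 at −6.48, the beta-glucosidase gene BGLU44 at −6.34 and AT1G73120 at −5.98. GUT2 read 13.16, 8.91 and 13.16 in the 3 DEX arrays, and replicate 2 sat nearest to DEX 12 h replicates 1 and 3. With the arrays out of place left out, 6952 were called. Centring each array on its median moved the median change of all probe sets by 0.25 and the share of rises among the calls from 37.5% to 49.5%.

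At 6 h 2241 probe sets rose and 2886 fell. AT3G19620 rose by 7.66 ± 1.01 (SE), from 4.56 ± 1.13 to 12.22 ± 0.17 (SD, n = 3). AT1G62170 rose by 7.35, AT1G21810 by 7.28 and AT4G39320 by 6.63. The wall-patterning gene KINESIN-13A rose by 2.41, and the cytokinin response gene ARR15 by 1.92. AT3G26450 changed by −6.17, AT5G62350 by −5.96 and the subtilase gene ATSBT5.2 by −5.30. The DMSO group included the out-of-place replicate 2, and AT1G66810 read 12.57 ± 0.15 against 4.53 ± 3.28 (DEX against DMSO). Leaving out the arrays out of place gave 2806 rises and 4180 falls, and a fit of the compared groups only gave 2653 calls.

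At 9 h 2683 probe sets rose and 4019 fell. AT1G66810 went from 2.71 ± 0.07 to 12.66 ± 0.21 (SD, n = 3), a rise of 9.95 ± 1.40 (SE, adjusted p = 1.5e-07). AT1G26290, AT1G24030, AT2G45040, AT1G09890, AT2G18720, AT4G21420 and AT1G29200 rose by 9.48, 9.47, 9.36, 9.36, 9.23, 9.15 and 9.13. IRX15, needed for normal xylan, rose by 8.89 and AT5G60720 by 8.79. The largest falls were AT4G11190 at −8.51, from 11.91 ± 0.25 to 3.40 ± 0.47 (SD, n = 3), and AT1G74470, which encodes geranylgeranyl reductase of the chlorophyll pathway, at −7.80. AT5G45670, BGLU44, AT1G09750, AT3G53980, AT1G29670, AT4G23820 and AT4G16980 changed by −7.75, −7.38, −7.35, −7.21, −7.20, −7.16 and −6.99. GH9C2, an endoglucanase gene, changed by −6.94. Without the arrays out of place, none of which carries a 9 h label, 2948 rose and 4307 fell.

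Among the fixed lists at 9 h, the 1 measured member of the 38 on the list of secondary wall regulators rose, AT1G66810, and the 1 measured member of the 18 on the wall-patterning list rose, KINESIN-13A by 2.58. All 4 measured xylan genes rose: IRX15, IRX15-L by 6.99, GUT2 by 6.41 and GUT1 by 1.19. Of 2 monolignol genes neither was called, with HCT at 0.68 and CCR2 at 0.15. Of 7 lignin polymerisation genes, all peroxidases, AT5G51890 rose by 3.74 and AT5G66390 by 2.96, whereas AT2G22420, AT2G41480 and AT4G33420 fell, at −3.06, −1.24 and −1.39 (camera adjusted p = 0.762, fry adjusted p = 0.229). Of 6 cell death genes, the aspartic protease gene AT4G04460 rose by 6.91 and AT4G18425 by 5.27, and the vacuolar processing enzyme gene GAMMA-VPE changed by −1.03 (camera adjusted p = 0.762, fry adjusted p = 0.229). Both shikimate pathway genes rose, AT1G22410 by 1.29 and AT5G66120 by 2.04. These counts were the same adjusted over the list alone.

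Of 7 primary wall genes 5 fell at 9 h, among them the cellulose-orienting gene COB at −1.78 and the expansin genes EXPA8 at −5.65 and EXPA9 at −3.41, but camera did not call the list, whereas fry, which does not compare it with other genes, called it down (camera adjusted p = 0.0856, fry adjusted p = 0.00203). Of 4 flavonoid genes DFR and UGT78D1 fell, at −4.47 and −2.60, and adjusted over the list alone 3 fell, with UGT78D2 at −2.14. Of 4 cambium genes LHW, PHV and CLE41 fell, at −1.89, −1.44 and −2.57, and CLE44 stood at 0.29. The chlorophyll and light-harvesting genes PORB and LHCB4.1 fell, at −6.58 and −3.22. Of 3 cell cycle genes AUR2 rose by 2.35, and AUR1 and PRL fell, at −1.59 and −3.13. Of 7 auxin response genes IAA30 rose by 5.28 and IAA29 by 2.65, while GH3.3, WES1 and LBD29 fell, at −3.87, −2.69 and −2.65 (camera adjusted p = 0.551, fry adjusted p = 0.0197). The cytokinin response gene ARR15 rose by 1.04, and RR16 stood at 0.25. Apart from the flavonoid genes, these counts were the same adjusted over the list alone.

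Few markers of other tissues and of stress were measured, 1 of 15 for phloem, 2 of 8 for root hairs, 1 of 21 for jasmonate, 1 of 18 for defence, 1 of 12 for heat shock and 1 of 13 for low oxygen, so these lists were hardly tested. At 9 h the phloem gene OPS stood at −0.74, the root hair expansins EXPA7 and EXPA18 at 0.66 and −0.01, the jasmonate gene PDF1.2 at 0.14, the defence gene WRKY53 at 1.40, the heat shock gene ATHSP22.0 at −0.84 and the low oxygen gene AT3G10040 at 0.76. The sugar starvation gene AT3G15450 rose by 1.15. None of 4 reference genes reached the fold minimum at 9 h, but 3 of them rose below it: PEX4 stood at 0.91 (adjusted p = 2.7e-06), AT4G26410 at 0.85 (adjusted p = 2.0e-08), AT2G28390 at 0.47 (adjusted p = 3.7e-04) and AT4G34270 at −0.19. At 6 h PEX4 was called, at 1.05. The 3' minus 5' difference of actin probe sets, a sign of RNA quality, averaged 1.18 ± 0.09 (SD) in 27 DMSO arrays of the VND7 line and 1.13 ± 0.14 in 24 DEX arrays.

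**Figure D3:**
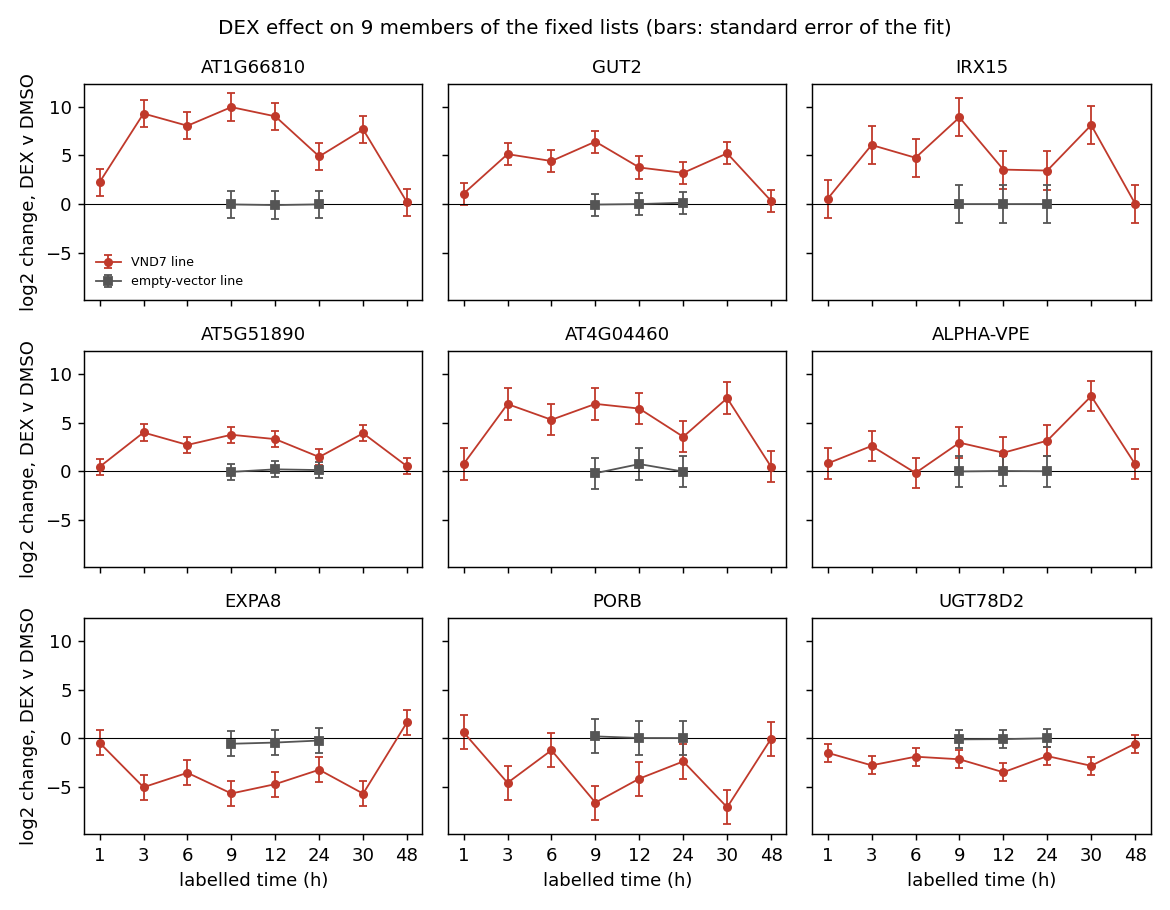
Log2 change of DEX against DMSO (vertical axis, bars: standard error of the fit, 3 arrays per group) at each labelled time in hours for 9 members of the fixed lists, VND7 line as circles and empty-vector line as squares. AT1G66810 stood at 9.95 at 9 h and 0.17 at 48 h, and EXPA8 at −5.65 and 1.66.

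Among the added lists, 19 of 24 genes noted for xylem and secondary walls rose at 9 h and AT1G80170 fell, at −2.36, with a median of 5.10 (camera adjusted p = 2.9e-07). The adjusted p was 0.698 with an estimated correlation. That correlation comes from residuals around the labelled groups, so arrays out of place can raise it. Here and below it was not estimated without them, and how much they raise it was not tested. Examples were AT2G41610 at 8.72, AT1G09440 at 8.57, AT1G63520 at 8.27 and AT3G62160 at 7.80. The list was called up at each of the 8 times at the preset correlation. At 3 h 19 members rose and 1 fell (adjusted p = 4.5e-07, and adjusted p = 0.993 with an estimated correlation). At 6 h 16 rose (adjusted p = 2.2e-05, and adjusted p = 0.656 with an estimated correlation). At 12 h 18 rose and 1 fell (adjusted p = 1.9e-06, and adjusted p = 0.777 with an estimated correlation). At 24 h 8 rose (adjusted p = 2.7e-07, and adjusted p = 0.732 with an estimated correlation). At 30 h 18 rose and 1 fell (adjusted p = 5.9e-09, and adjusted p = 0.381 with an estimated correlation). At 1 h (adjusted p = 0.00253, and adjusted p = 0.821 with an estimated correlation) and 48 h (adjusted p = 0.0477, and adjusted p = 0.724 with an estimated correlation) no single member was called.

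Expansins and the TBL and GH9 families had members going both ways. Of 18 expansins and relatives 3 rose and 8 fell at 9 h (camera adjusted p = 0.346, fry adjusted p = 4.2e-06), EXPA21 at 4.14 and EXPB1 at 2.30 against EXPB3 at −4.25 and EXLB1 at −4.00. Of 9 xyloglucan endotransglucosylases 5 fell and 0 rose, XTH16 at −5.19 and XTH19 at −4.52 among them (camera adjusted p = 0.0856, fry adjusted p = 0.00165). Of 22 members of the TBL family of wall acetylation 1 rose, TBL34 at 6.50, and 6 fell (camera adjusted p = 0.551, fry adjusted p = 0.00445). Of 15 GH9 endoglucanases 4 rose, GH9B18 at 5.92 and GH9B5 at 5.02 among them, and 3 fell, GH9B13 at −6.66 among them (camera adjusted p = 0.762, fry adjusted p = 0.0179).

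At 12 h 2034 probe sets rose and 3005 fell. AT5G49690 rose by 8.55 ± 1.55 (SE), from 2.71 ± 0.31 to 11.26 ± 0.48 (SD, n = 3). AT5G45320 rose by 7.85, AT3G62160 by 7.24 and AT3G47400 by 6.93. DFR, which makes anthocyanin precursors, changed by −6.03 to the floor, and the wall gene XTH16 by −5.59. AT2G04570, AT4G37550, AT3G04760 and AT1G14120 changed by −6.30, −5.84, −5.36 and −5.28. GUT2 read 9.05, 13.15 and 8.90 in the 3 DEX arrays, and replicate 2 sat nearest to arrays labelled DEX 3 h and 9 h. The total was 5959 without the arrays out of place.

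At 24 h 657 probe sets rose and 333 fell, with 1 array of each group out of place. AT1G21810 rose by 5.46 ± 0.78 (SE), from 3.09 ± 0.68 to 8.55 ± 0.70 (SD, n = 3). AT1G63520 rose by 4.93, AT1G06170 by 4.85 and NCRK by 4.66. The wall genes GH9B18 and TBL34 rose by 4.46 and 4.20, and AT2G20720, AT1G75730 and AT1G62170 by 3.94, 3.87 and 3.87. Lower were AT5G01210 at −3.56, FMO at −2.68, AT3G61820 at −2.45, AT2G44670 at −2.43 and AT2G38180 at −2.28. Leaving out DMSO replicate 1, 2 or 3 gave 3236, 369 or 443 calls, and leaving out DEX replicate 1, 2 or 3 gave 269, 3755 or 310. The counts were 3024 up and 3898 down without the arrays out of place, and a fit of the compared groups only gave 1 call.

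At 30 h 2900 probe sets rose and 3461 fell. AT3G10590 rose by 9.39 ± 1.62 (SE), from 2.16 ± 0.02, at the floor, to 11.55 ± 0.48 (SD, n = 3, adjusted p = 1.1e-04). AT1G10810, AT3G07450, AT1G17310 and AT4G23110 also started at the floor and rose by 8.91, 8.66, 8.55 and 8.16. AT5G19870 rose by 8.46 and AT1G14240 by 8.15. AT1G74470 fell again, at −8.43, and PRK, the phosphoribulokinase gene of carbon fixation, changed by −7.70. AT5G05960, AT3G16370, AT3G05730, the defensin-like gene LCR68 and AT4G01310 changed by −7.63, −7.53, −7.48, −7.48 and −7.46. When the arrays out of place were left out, 3112 rose and 3610 fell.

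Genes of lignin and cell death were called at 30 h that had missed the threshold at 9 h, a change that was not itself tested. Missing the threshold does not show that a gene was unchanged at 9 h. The cell death gene ALPHA-VPE read 7.94, 5.76 and 6.16 in the DEX arrays of 9 h, and 4.06 in the highest DMSO array of that time. At 30 h the cinnamoyl-CoA reductase gene CCR2 rose by 4.48 and the peroxidase gene PRX52 by 5.13, and HCT stood at 0.98. Of the lignin polymerisation genes 3 rose, PRX52, AT5G51890 at 3.90 and AT5G66390 at 3.57, and AT2G22420 fell, at −1.06 (camera adjusted p = 0.358, fry adjusted p = 0.0727). ALPHA-VPE rose by 7.71, AT4G04460 by 7.50 and AT4G18425 by 6.81, so 3 of 6 cell death genes rose (camera adjusted p = 0.29, fry adjusted p = 0.0307). Of the xylan genes 3 rose, GUT2 by 5.21, IRX15 by 8.10 and IRX15-L by 6.10. The primary wall list was called down at the preset correlation, with 4 of 7 members down, or 5 adjusted over the list alone (camera adjusted p = 0.00325, and adjusted p = 0.403 with an estimated correlation). EXPA8 changed by −5.66. The xyloglucan endotransglucosylases were called down too, with 5 of 9 members down (camera adjusted p = 0.00219, and adjusted p = 0.381 with an estimated correlation). Of other fixed lists, 2 shikimate genes and 2 root hair genes rose, EXPA7 by 1.53 and EXPA18 by 2.05, as did WRKY53 by 2.56. AT3G15450 rose by 1.13. Falls numbered 3 of 4 flavonoid, 3 of 4 cambium, 2 of 2 chlorophyll and 2 of 3 cell cycle genes. No measured phloem, cytokinin, jasmonate, heat shock, low oxygen or reference gene was called. Apart from the primary wall list, these counts were the same adjusted over the list alone. Of 7 auxin genes 1 rose and 3 fell (camera adjusted p = 0.249, fry adjusted p = 0.0307).

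At 48 h only 1 probe set passed, a fall, and it does not name a single gene. The 3 DEX arrays at this time are among those out of place, so no value can be had without them. AT1G66810 stood at 0.17, GUT2 at 0.32 and EXPA8 at 1.66. At an unadjusted p under 0.05 limma gave 1580 probe sets. Leaving out DMSO replicate 1 or 3 gave 11 or 3 calls, and leaving out DEX replicate 1, 2 or 3 gave 6, 13 or 0. A fit of the compared groups only gave 0.

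Onsets were counted with all arrays first. Taking the onset as the earliest time of a call that held in the same direction at the next time, 5344 probe sets had one. At 3 h 1639 rises and 2410 falls set in, at 6 h 167 and 144, at 9 h 244 and 625, and at 24 h 85 and 12. An onset at 30 h needs the same call at 48 h, where the DEX arrays are out of place, so none was counted. With the times ending at 30 h, all arrays gave 8359 onsets, of which 1663 rises and 1353 falls set in at 30 h, beside the 1639 and 2410 at 3 h. Of members of the lists, 39 rises and 42 falls began at 3 h. At 3, 6, 9, 12 and 30 h together 858 probe sets were called up and 1411 down each time, against 0.314 and 1.78 expected if the times were independent. The times are not independent, because they share 1 fitted spread per probe set, and values at the floor can hardly be called. More overlap than expected was therefore fixed in part beforehand. Without the arrays out of place, over the same shorter times, 1571 rises and 3048 falls set in at 1 h and 780 and 927 at 3 h. That earlier onset rests on the array labelled DEX 1 h replicate 1, so the time of onset stays open.

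In the empty-vector line DEX raised a small set of genes. AT1G28160 rose from the floor by 2.49 ± 0.07 (SE) at 9 h, 3.32 at 12 h and 3.45 at 24 h. Its 3 DEX arrays at 9 h had an SD of 0.28. The standard error draws on all arrays and understates this spread, as does that of its average given below. AT3G15720 rose by 2.64, 2.89 and 2.88, and AT4G31470 by 2.62, 2.96 and 2.23. AT4G14650 rose by 2.11 at 9 h, AT3G02500 by 1.56 at 9 h, AT3G50570 by 1.92 at 12 h and AT1G78460 by 2.21 at 24 h. AT4G15660 fell at 9 h, at −1.31, and AT1G06830 and AT5G38020 at 24 h, at −1.81 and −1.74. The calls were 16 up and 3 down at 9 h, 20 up and 0 down at 12 h, where limma gave 322 probe sets at an unadjusted p under 0.05 in both directions together, and 21 up and 7 down at 24 h. The same 13 probe sets rose at all 3 times, against 1.3e-05 expected of independent lists. The 3 lists share 1 fitted spread per probe set, so they are not independent. No fixed list was called at any of these times. Without the arrays out of place, which are all of the other line but share the fitted spread, the counts were 41, 44 and 51. A fit of the compared groups only, which shares no spread with the other line, gave 5, 4 and 6.

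The difference of the DEX effect between the lines was tested to tell the VND7 response from that to DEX with VP16-GR but no VND7. At 9 h the effect was larger in the VND7 line for AT1G66810 by 9.98 ± 1.98 (SE), AT1G26290 by 9.45, AT1G09890 by 9.36 and AT1G24030 by 9.30. AT4G11190, AT3G53980, AT5G45670, BGLU44 and AT1G74470 differed by −8.58, −7.70, −7.61, −7.38 and −7.26. The effect was higher in the VND7 line for 2239 probe sets and lower for 2980 at 9 h, for 1368 and 1689 at 12 h, and for 31 and 38 at 24 h. At 12 h AT1G66810 differed by 9.10, AT5G49690 by 8.48, AT1G80130 by −7.15, DFR by −6.03 and XTH16 by −5.94. At 24 h AT1G21810 differed by 5.47, AT1G06170 by 4.84, AT1G28160 by −3.45 and AT3G15720 by −3.21. Of the xylem and secondary wall list 18 members were higher and 1 lower at 9 h (camera adjusted p = 5.9e-07, and adjusted p = 0.626 with an estimated correlation). At 12 h 12 were higher and 1 lower (adjusted p = 8.2e-06, and adjusted p = 0.942 with an estimated correlation). At 24 h none was called (adjusted p = 5.9e-06, and adjusted p = 0.711 with an estimated correlation). The 24 h total of 69 became 36 or 42 without empty-vector DMSO replicate 1 or 2, and 43, 31 or 42 without its DEX replicates 1, 2 or 3. It became 186, 40 or 43 without VND7-line DMSO replicates 1, 2 or 3, and 29, 1254 or 34 without its DEX replicates. The totals were 6892, 5246 and 6253 without the arrays out of place.

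Without DEX the lines already differed. AT2G04850 was higher in the VND7 line by 5.57 ± 0.25 (SE) at 9 h, 5.44 at 12 h and 5.43 at 24 h. AT2G36710 was higher by 5.35, 5.93 and 5.45, AT1G13470 by 5.12, 5.81 and 6.21, and DFR by 6.03 at 12 h. AT2G16005 was lower, at −5.05, −4.90 and −4.31, as was AT1G72140, at −4.83, −3.80 and −3.66. AT5G55620 was lower at −3.75, −3.19 and −4.46. In all 158 probe sets were higher and 179 lower at 9 h, 213 and 297 at 12 h, and 229 and 286 at 24 h, of which 103 were higher and 73 lower at all 3 times. Of the xylem and secondary wall list 1 member was higher at 9 h (camera adjusted p = 0.0259, and adjusted p = 0.83 with an estimated correlation) and 3 at 24 h (adjusted p = 1.7e-05, and adjusted p = 0.5 with an estimated correlation). The 24 h DMSO group holds an array out of place. The 9 h total of 337 became 197 without empty-vector replicate 1 and 210 without VND7-line replicate 2. The 12 h total of 510 became 298 or 315 without empty-vector replicate 1 or 2, and 266 without VND7-line replicate 1. The 24 h total of 515 became 311 or 335 without empty-vector replicate 1 or 2, and 266, 879 or 869 without VND7-line replicate 1, 2 or 3. The totals were 843, 1281 and 612 without the arrays out of place, and 530 at 9 h and 58 at 24 h in a fit of the compared groups only. Each line was one stock, so line and culture batch cannot be told apart.

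In DMSO alone, 0 probe sets were called at 24 h and 0 at 48 h against 0 h in the VND7 line. Limma gave 2044 and 803 at an unadjusted p under 0.05. At 24 h AT1G66810 stood at −0.31 and GUT2 at 0.79 against 0 h, with an array out of place in both groups, DMSO 24 h replicate 1 and DMSO 0 h replicate 3. The xylem and secondary wall list was called down at 48 h with no member called (camera adjusted p = 8.5e-05, and adjusted p = 0.953 with an estimated correlation). The lignin polymerisation list was called up at 24 h in the same way (adjusted p = 2.1e-04, and adjusted p = 0.249 with an estimated correlation). Neither list was called without the arrays out of place (adjusted p = 0.749 at 48 h and 0.0890 at 24 h). At 24 h the total became 14 or 2 without 0 h replicate 2 or 3, 23 or 28 without 24 h replicate 2 or 3, and 2 without the arrays out of place. At 48 h it became 3, 5 or 2 without 0 h replicate 1, 2 or 3, 2 or 1 without 48 h replicate 1 or 3, and 0 without the arrays out of place.

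The response was tested for change between times, although DEX arrays of different times sat together. Trios of mutually nearest arrays joined DEX 3 h replicate 1 with 9 h replicate 1 and 12 h replicate 2, and 3 h replicate 3 with 9 h replicates 2 and 3. The rule for arrays out of place looks at treatment labels alone, so few calls between 3 and 9 h do not show that the response held still. From 3 to 9 h 4 probe sets went up and 4 down: AT1G52770 by 1.12, AT1G65760 by 1.09, AT2G32560 at −2.80 and AT3G58020 at −1.14 were those with a single gene. Without the arrays out of place AT3G58020 lost its call (limma adjusted p = 0.0910), and AT1G52770, AT1G65760 and AT2G32560 kept theirs. From 9 to 24 h 404 went up and 499 down. The 24 h groups hold the out-of-place arrays DMSO replicate 1 and DEX replicate 2, and all 3 DEX arrays of 48 h are out of place. The effect on AT3G53980 went up by 5.77, the subtilase gene ATSBT5.2 by 5.61, AT5G62350 by 4.64, AT1G30760 by 3.79 and AT4G30460 by 3.52. The rises of AT3G53980, ATSBT5.2 and AT5G62350 without the arrays out of place were 3.78, 4.18 and 4.40, all called. The carboxypeptidase gene SCPL43 went down, at −6.33, as did AT4G39320, AT5G38310 and AT3G58540, at −4.79, −4.66 and −4.59. The falls of these genes without the arrays out of place were −6.236, −5.705, −2.817 and −3.912, all called. From 24 to 48 h 102 went up and 41 down, AT1G69570 and TRM26 by 3.74 and 3.04, and AT1G21810 and AT1G06170 at −5.69 and −4.88. The xylem and secondary wall list was called down from 9 to 24 h (camera adjusted p = 9.4e-04, and adjusted p = 0.863 with an estimated correlation) and from 24 to 48 h (adjusted p = 8.3e-04, and adjusted p = 0.525 with an estimated correlation). The fall from 9 to 24 h was not called without the arrays out of place (adjusted p = 0.0986), with a median of −0.32 against −2.37 with all arrays, and the later interval has no value. With all arrays, in the earlier interval 1 member was called, AT1G07120 at −3.96, and in the later 1 went the other way, AT1G72230 at 1.57. KINESIN-13A went down in both, at −1.28 and −1.21.

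Single arrays moved these totals. From 3 to 9 h the 8 became 21 without DMSO 3 h replicate 2, 32, 19 or 43 without DEX 3 h replicate 1, 2 or 3, and 30, 17 or 16 without DEX 9 h replicate 1, 2 or 3. From 9 to 24 h the 903 became 1539 or 529 without DEX 24 h replicate 1 or 2. From 24 to 48 h the 143 became 396, 80 or 32 without DMSO 24 h replicate 1, 2 or 3, and 90, 41 or 41 without those of 48 h. It became 7, 1085 or 21 without DEX 24 h replicate 1, 2 or 3, and 88 or 0 without DEX 48 h replicate 1 or 3. Without the arrays out of place the first 2 totals were 14 and 1822. A fit of the compared groups only gave 1, 145 and 18.

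Averaged over the 8 times, 1686 probe sets rose and 2825 fell in the VND7 line, and without the arrays out of place 6713 were called. AT1G66810 rose by 6.40 ± 0.49 (SE), AT2G45040 by 6.17, AT5G49690 by 6.03, AT1G29200 by 5.87 and AT5G45320 by 5.83. AT1G80130, BGLU44, AT1G74470, AT4G16980 and GSTU20 changed by −5.14, −4.61, −4.41, −4.37 and −4.24. The xylem and secondary wall list had 19 members up and 1 down (camera adjusted p = 1.1e-07, and adjusted p = 0.885 with an estimated correlation). In the empty-vector line 46 rose and 4 fell on average, AT1G28160 by 3.09 ± 0.04 (SE), AT1G19900 by 1.95, and AT2G29290 and AT4G15660 at −1.59 and −1.13. The total of 50 became 33 without replicate 3 of every group, 73 without the arrays out of place and 79 in a fit of the compared groups only. Of these rises 3 were also called up in the VND7 average, against 3.41 expected of independent lists, and 8 were called down there. The 2 averages cover unlike times, 8 in the VND7 line and 3 in the empty-vector line. The average difference between the lines was higher for 1908 and lower for 3089 probe sets, with AT1G66810 at 8.00, AT5G49690 at 7.47, AT1G80130 at −5.80 and AT5G45670 at −5.40. The xylem and secondary wall list had 19 members higher and 1 lower (adjusted p = 3.0e-07, and adjusted p = 0.665 with an estimated correlation). This total of 4997 became 3245 without replicate 3 of every group and 6641 without the arrays out of place.

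The size of a change depends on the floor where the lower group mean lay there. This held for AT2G45040 and IRX15 at 3 h, AT1G62170 at 6 and 24 h, and AT2G45040, AT2G18720, AT4G21420, IRX15, IAA30, ARR15, RR16, PDF1.2, EXPA21 and GH9B18 at 9 h. It also held for AT1G06170 and GH9B18 at 24 h, and for IRX15, CCR2, PRX52 and PRK at 30 h. DFR lay at the floor with DEX at 9 and 12 h and in the empty-vector line, AT4G37550 with DEX at 12 h, AT1G28160 and AT3G02500 in the empty-vector line with DMSO, and AT1G72140 in the VND7 line with DMSO. For a change between times, a group mean at the floor entered the values of AT1G52770, AT1G65760, AT2G32560 and AT3G58020 from 3 to 9 h, SCPL43 from 9 to 24 h and AT1G06170 from 24 to 48 h.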

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

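All tests of explanations and all other splits of the arrays in this part were chosen after the results were seen.

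In these results the effect of DEX differed between the lines or between times in a test of the difference itself. Between the lines it differed for 5219 probe sets at 9 h, 3057 at 12 h and 69 at 24 h, and on average for 4997. In the VND7 line it changed for 8 probe sets from 3 to 9 h, 903 from 9 to 24 h and 143 from 24 to 48 h, with 1 array of each 24 h group and all DEX arrays of 48 h out of place. AT1G66810, the zinc finger gene, led the difference at 9 h with 9.98 ± 1.98 (SE). The carboxypeptidase gene SCPL43 led the falls from 9 to 24 h at −6.33, with a group mean at the floor.

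For the averages, 100 random splits were drawn, the real one included. The VND7 average called 4511 probe sets and its highest other split 2912, the empty-vector average 50 and 8, and the average difference 4997 and 4752, with 1 draw of 100, the real one, as large in each. A draw can leave the labels of some pairs of groups in place, and arrays out of place were among those shuffled. The shares therefore argue against chance but do not exclude it.

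For a single difference or change, about 1 draw in 10 leaves the labels of 1 pair of groups in place by design, and the effect of that pair stays, so these splits decide nothing about chance. For the difference at 9 h 9 of 100 splits were as large, with 5219 real and 5468 at most, and the draws that moved the VND7-line arrays reached 13. At 12 h 4 of 100 were as large, with 3057 real and 3574 at most, and such draws reached 16. At 24 h 12 of 100 were as large, with 69 real and 5095 at most, which was also reached with the VND7-line arrays moved and points to a structure of the arrays. For the changes 38, 16 and 12 of 100 were as large, with 8, 903 and 143 real and 8613, 9969 and 6388 at most.

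With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the VND7 line 7 of 10 were as large at 1 h, with 3 real and 3804 at most, where DMSO replicate 2 and DEX replicate 2 were exchanged. At 24 h 2 of 10 were as large, with 990 real and 6446 at most, where DMSO replicate 1 and DEX replicate 2 were exchanged. Both highest values point to a structure of the arrays. The real split was the only 1 of 10 as large at 3 h with 6317 against 1565, 6 h with 5127 against 639, 9 h with 6702 against 5, 12 h with 5039 against 307 and 30 h with 6361 against 2. At 48 h 2 of 10 gave 1 call. The real split was also alone for the empty-vector line, with 19 against 1, 20 against 4 and 28 against 3, and for the lines without DEX, with 337 against 1, 510 against 1 and 515 against 12. For DMSO against 0 h all 10 were as large as 0, and the highest gave 10 calls at 24 h and 2 at 48 h.

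Arrays of the VND7 line sat with the other treatment label, 3 labelled DMSO and 6 labelled DEX. Among the latter, DEX 1 h replicate 2 and DEX 24 h replicate 2 were intermediate, with xylem and secondary wall list means of 7.31 and 7.26. After quantile normalization 9 arrays were nearer to the other label and 9 before, but that step keeps the order of values within an array, so the count would hardly move. In the 3 arrays labelled DMSO the xylem and secondary wall list averaged 8.80, 8.48 and 8.54, and the primary wall list 6.59, 6.84 and 6.80. In the other DMSO arrays but 0 h replicate 3 they averaged 5.19 to 5.90 and 8.23 to 8.76. This reversed order argues against an order-keeping normalization as the cause in those 3 arrays. For the other arrays normalization stays open. Exchanged array labels may account for the pattern: 10 of 11 trios of mutually nearest arrays carried more than 1 group label, though times with similar profiles would also mix trios. DMSO 1 h replicate 2, 6 h replicate 2 and 24 h replicate 1 formed a trio (lowest r within 0.975, highest to any other array 0.962). DMSO 0 h replicate 3, DEX 1 h replicate 2 and DEX 24 h replicate 2 formed another (0.977 and 0.934). This last trio mixes treatments, which similar times alone would not give. Cultures that responded otherwise than treated, through a leaky, failed or ended induction, are another explanation. On the first principal component the VND7-line arrays formed 2 parts, the upper down to −7.41 and the lower up to −41.6. The upper part held 24 arrays, as many as carried a DEX label. Each of these belonged to a trio of mutually nearest arrays within that part. This argues against unrelated leaks and failures of single cultures, which would hardly restore that number in sets of 3. An ended induction at 48 h is not excluded by it. The probe sets raised at 30 h had a median log2 change of 0.20 at 48 h against 2.0 at 30 h, and both explanations predict that.

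The VND7 line differed from the empty-vector line without DEX, with DFR 6.03 higher at 12 h and AT2G16005 at −5.05 at 9 h. The falls do not exclude a leak of the construct. At 9 h 25 of 179 were also lowered by DEX at 30 h against 27.2 expected of independent lists, with 5 the other way against 22.8 expected. At 12 h it was 48 of 297 against 45.2, with 18 the other way against 37.9. At 24 h it was 111 of 286 against 43.5, with 2 the other way against 36.5, in a DMSO group that holds an array out of place. Among the rises a leak may account for a part. At 9 h 59 of 158 were also raised at 30 h against 20.1 expected, with 23 the other way against 24.0 expected. At 12 h it was 60 of 213 against 27.2, but 52 went the other way against 32.4, an excess in both directions. At 24 h it was 119 of 229 against 29.2, with 10 the other way against 34.8, in the DMSO group that holds an array out of place. The insertion site, the seed stock or the culture batch could give the 103 probe sets higher at all 3 times, against 0.0149 expected, and they cannot be told apart because line and batch coincide.

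DEX raised 46 probe sets on average in the empty-vector line, with AT1G28160 first at 3.09 ± 0.04 (SE). These probe sets did not rise as a set in the VND7 average. Their median change there was −0.0762, with quartiles of −0.71 and 0.04, against 1.41 in the empty-vector line. Of the 46, 16 were above 0 in the VND7 line. The activated VP16-GR protein of the vector is another possible cause. The VND7 line carries it too, within its fusion, and the 13 probe sets that rose at all 3 times do not tell it from DEX itself. No line without a construct was compared, so both causes stay open.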

How the results depend on the processing

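Leaving out the 10 arrays out of place was chosen after the data were seen, and the other alternatives before. Those arrays were picked from the same values, so higher counts without them follow in part from the choice. With the constant prior, the robust prior and quantile normalization, each of the 25 totals stayed within 1.5 times its value. The 2 priors, the dim filter, the fit of the compared groups only, no minimum change and the pooled adjustment leave each change as it was. These settings could not turn a direction. None of the 1332 gene and comparison pairs named, all picked because they were called, turned direction under any alternative. Of these, 3 lost their call with the constant prior, 2 with the robust prior, 94 with quantile normalization, 50 with median centring, 266 with only the compared groups, 39 with array weights, 64 with the replicate block and 26 of 1319 without the 10 arrays. Of 1073 pairs 51 lost it with the pooled adjustment, and of 8517 checks that left out an array or a replicate 1165 did. The dim filter lost none of the 1296 it kept. Of 30 list calls, those of all comparisons but DMSO against 0 h and the changes between times, 25 were kept with the dim filter, 27 with quantile normalization, 24 with centring, 26 with the block, 30 with the mean of a gene's probe sets, 14 with fry, 24 of 25 without the 10 arrays and 0 with an estimated correlation. Centring moved the median change of all probe sets by up to 0.25 and the share of rises at 3 h from 37.5% to 49.5%, and from 24 to 48 h from 71.3% to 52.1%. The total of 5344 onsets was 3884 with only the compared groups, its lowest, and 7917 with array weights. Without the 10 arrays it was 8942, because the times then end at 30 h, where a single call counts; all arrays gave 8359 over the same times. Values at the floor limit how large a fall can be measured.

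The dim filter, which tests fewer probe sets, gave 1 call at 1 h, 0 at 48 h, 14 in the empty-vector line at 24 h and 0 from 3 to 9 h. Median centring gave 71 from 24 to 48 h, and the cause was not tested. Only the compared groups, with fewer arrays to estimate the spread, gave 0 at 1 h, 2653 at 6 h, 1 at 24 h and 0 at 48 h in the VND7 line, and 5, 4 and 6 in the empty-vector line. It gave 530 and 58 for the lines without DEX at 9 and 24 h, 1, 145 and 18 for the changes, and 79 for the empty-vector average. No fold minimum, which admits small changes, gave 12 at 1 h, 9782 at 3 h, 8023 at 6 h, 7961 at 12 h, 1828 at 24 h and 4 at 48 h. It gave 31 and 45 in the empty-vector line at 9 and 24 h, 602, 899 and 928 for the lines without DEX, 2 and 1 for DMSO against 0 h, 57 from 3 to 9 h, and averages of 13462, 122 and 8561. The pooled adjustment gave 145 at 1 h, 147 at 48 h, 490 for the difference at 24 h, 19 from 3 to 9 h and 219 from 24 to 48 h, and the cause was not tested.

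Array weights, which lower the part of arrays unlike their group, gave 77 at 1 h, 6270 at 24 h and 403 at 48 h. They gave 97, 91 and 111 in the empty-vector line, 5420 and 6000 for the differences at 12 and 24 h, 1235, 1592 and 1180 for the lines without DEX, 197 and 4 for DMSO against 0 h, 37, 1587 and 5155 for the changes, and 80 for the empty-vector average. The replicate block gave 1 at 1 h, 208, 300 and 294 for the lines without DEX and 73 from 24 to 48 h, and the cause was not tested. Without the 10 arrays the values were 6950 at 1 h, 6922 at 24 h, 41, 44 and 51 in the empty-vector line, and 5246 and 6253 for the differences at 12 and 24 h. They were 843 and 1281 for the lines without DEX at 9 and 12 h, 2 for DMSO at 24 h, and 14 and 1822 for the changes to 9 and 24 h. No value can be had at 48 h then. The 18 list calls at the 8 times became 0 with an estimated correlation, 42 with fry and 34 without the 10 arrays. The correlation was estimated with the 10 arrays included, which can raise it, and the estimate was not repeated without them.

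Leaving out 1 array gave 3 to 312 at 1 h (highest without DEX replicate 3), 5454 to 6965 at 3 h, 4212 to 6290 at 6 h, 6276 to 6606 at 9 h, 4253 to 5157 at 12 h, 269 to 3755 at 24 h (without DEX replicates 1 and 2), 5514 to 6137 at 30 h and 0 to 13 at 48 h (without DEX replicates 3 and 2). In the empty-vector line it gave 17 to 23, 18 to 26 and 21 to 29. For the differences it gave 4500 to 4974, 2393 to 3082 and 29 to 1254 (without VND7-line DEX 24 h replicates 1 and 2). For the lines without DEX it gave 197 to 329 (lowest without empty-vector replicate 1), 266 to 559 (lowest without VND7-line replicate 1) and 266 to 879 (without VND7-line replicates 1 and 2). For DMSO against 0 h it gave 0 to 28 (highest without 24 h replicate 3) and 0 to 5 (highest without 0 h replicate 2). For the changes it gave 6 to 43 (highest without DEX 3 h replicate 3), 529 to 1539 (without DEX 24 h replicates 2 and 1) and 0 to 1085 (without DEX 48 h replicate 3 and DEX 24 h replicate 2). Leaving out a replicate number gave 4061 to 5261 for the VND7 average, 33 to 38 for the empty-vector average and 3245 to 4927 for the average difference, the latter pair lowest without replicate 3.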

Other observations

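Families outside the fixed lists were described with lists added before the change of any gene was computed, and the examples and array correlations below were chosen after. Of 43 photosynthesis genes of the plastid genome 2 rose and 0 fell at 9 h, ndhE by 1.16 and ndhK by 1.75, and 29 fell at 30 h. Among the falls were psaA at −4.93 ± 1.22 (SE), psbC at −4.30 and rbcL at −2.08. Their median was −1.83 at 30 h (camera adjusted p = 4.6e-09, and adjusted p = 0.483 with an estimated correlation). Autophagy genes went the other way. Of 10 ATG8 and ATG3 genes 3 rose at 9 h and 8 at 30 h (camera adjusted p = 7.3e-05, and adjusted p = 0.465 with an estimated correlation), with ATG8H at 3.54 ± 0.74 (SE), APG8A at 2.76 and ATG8B at 2.01. Of 13 touch and stress genes 1 rose and 1 fell at 9 h and 5 rose at 30 h (camera adjusted p = 0.0185, and adjusted p = 0.511 with an estimated correlation), GRX480 by 4.77 and WRKY6 by 2.50 among them. This list was also called up at 1 h with no member called and a median of 0.77 (camera adjusted p = 0.00593, and adjusted p = 0.821 with an estimated correlation). The 4 other lists called at 48 h had no member called: auxin response, plastid and cell division genes, and ATG8 and ATG3, at camera adjusted p of 0.0287, 1.9e-08, 0.00295 and 0.0477. The adjusted p was 0.534, 0.534, 0.534 and 0.724 with an estimated correlation.

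Camera called none of the following lists at 9 or 30 h, but fry, which does not compare a list with other genes, called some. Fry called the tetraspanins down at 9 h (adjusted p = 0.00245). At 30 h it called the tubulins (0.0113), cell division genes (0.0307), expansins (3.2e-05) and TBL genes (0.0321) down, and GSTU genes (0.0113) and beta-glucosidases (0.0456) up. At 9 h it also called expansins (4.2e-06) and TBL genes (0.00445) down and GH9 genes (0.0179) up. Of 14 SWEET sugar transporters 2 fell at 9 h, SWEET1 at −3.48 and SWEET3 at −2.35, and at 30 h 3 rose, SWEET2 by 5.41 among them, and 3 fell, SWEET11 at −5.14 among them. Of 47 UGT glycosyltransferases 2 rose and 10 fell at 9 h, UGT74F1 at 3.77 and UGT88A1 at −2.80 among them, and 5 rose and 6 fell at 30 h. Of 11 GSTU glutathione transferases 3 rose and 2 fell at 9 h, GSTU25 at 5.10 and GSTU20 at −6.38 among them, and 5 rose and 1 fell at 30 h. Of 29 serine carboxypeptidases 5 rose and 7 fell at 9 h, with SCPL43 at 6.40 and scpl35 at −4.26, and 8 rose and 8 fell at 30 h, with scpl30 at 6.13. The DMSO means of SCPL43 and BGLU41 at 9 h and of scpl30 at 30 h lay at the floor. Of 20 beta-glucosidases 1 rose at 9 h, BGLU41 by 7.26, and 3 fell, and at 30 h 5 rose and 3 fell. Of 15 tetraspanins 5 fell at 9 h, TET2 at −2.92 among them, and 1 rose and 2 fell at 30 h. Of 7 tubulins TUB5 fell at 9 h, at −3.24, and 4 fell at 30 h, TUB1 at −3.34 among them. Of 11 cell division genes 2 rose and 4 fell at 9 h, ATMAP65-6 at 1.87 and TOPII at −1.94 among them, and 4 fell at 30 h. Of 12 cold and dehydration genes COR27 rose by 4.08 and COR47 fell, at −1.75, at 9 h, and 3 rose and 1 fell at 30 h. At 30 h 5 expansins rose and 7 fell, 1 TBL gene rose and 4 fell, and 4 GH9 genes rose and 3 fell.

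Some lists were called outside the DEX effect of the VND7 line. The plastid genes were lower in the empty-vector line with DEX at 24 h with no member called (camera adjusted p = 0.0077, and adjusted p = 0.959 with an estimated correlation). Without DEX they were lower in the VND7 line, with 5 members at 9 h (adjusted p = 1.5e-04, and adjusted p = 0.83 with an estimated correlation) and 3 at 24 h (adjusted p = 1.3e-15, and adjusted p = 0.5 with an estimated correlation). With no member called, the ATG8 and ATG3 genes were lower there at 12 h (adjusted p = 0.0477, and adjusted p = 0.98 with an estimated correlation). The touch and stress genes were higher at 24 h, also with no member called (adjusted p = 9.8e-04, and adjusted p = 0.5 with an estimated correlation). The 24 h DMSO group of the VND7 line holds the out-of-place replicate 1. The touch and stress genes were not called at 24 h without the arrays out of place (adjusted p = 0.569), while the plastid genes stayed lower with a median of −0.45 instead of −1.53 (adjusted p = 8.9e-05).

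In DMSO alone at 24 h against 0 h 2 more lists were called up and 2 down, with no member called. The ATG8 and ATG3 genes (camera adjusted p = 1.5e-04, and adjusted p = 0.373 with an estimated correlation) and the touch and stress genes (adjusted p = 5.2e-05, and adjusted p = 0.373 with an estimated correlation) were higher. The plastid genes (adjusted p = 1.4e-15, and adjusted p = 0.373 with an estimated correlation) and the cell division genes (adjusted p = 0.0291, and adjusted p = 0.432 with an estimated correlation) were lower. The out-of-place arrays DMSO 24 h replicate 1 and DMSO 0 h replicate 3 are in these groups, and without the arrays out of place none of the 4 lists was called. The adjusted p was then 0.0764 for the ATG8 and ATG3 genes, 0.264 for touch and stress, 0.0764 for plastid and 0.402 for cell division genes. For the change of the DEX effect from 24 to 48 h, the xyloglucan endotransglucosylases were called up (camera adjusted p = 0.027, and adjusted p = 0.505 with an estimated correlation) and the plastid genes down (adjusted p = 2.6e-05, and adjusted p = 0.598 with an estimated correlation), each with no member called. All 3 DEX arrays of 48 h and 1 array of each 24 h group are out of place, and no value can be had without them.

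The closest arrays did not follow the time labels evenly. In the VND7 line the nearest array among those of the same treatment carried the same time label for 2 of 27 DMSO arrays (permutation p = 0.582) and 13 of 24 DEX arrays (permutation p = 4.0e-05). In the empty-vector line it did for 6 of 9 DMSO arrays (permutation p = 0.0213) and 6 of 9 DEX arrays (permutation p = 0.0152), one-sided tests. In the empty-vector line 5 arrays had a higher median correlation with the other treatment label. The highest correlation between arrays across probe sets, 0.994, joined DMSO 30 h replicate 1 and DEX 48 h replicate 1 of the VND7 line, and no 2 columns were identical. Probe sets are not independent replicates.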
